A study of Bos taurus with 8 samples.

How the data were processed

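RNA of granulosa cells, the somatic cells that line the follicle, was compared on 8 two-colour oligonucleotide arrays. Per the labels, cells were aspirated from dominant follicles larger than 9 mm of Holstein cows at day 60 postpartum, 42 h after one prostaglandin injection. Cows with severe negative energy balance and high blood beta-hydroxybutyrate form group BHBH, and cows with mild negative energy balance form group BHBL. Each group held 12 cows in 4 pools of 3. RNA was extracted with PicoPure and linearly amplified with RiboAmp HSPlus, and 825 ng per pool were labelled by the ULS method. Every pool was hybridised on 2 dye-swapped arrays. Slide 289 carried BHBH in Cy5 and slide 288 carried BHBL in Cy5. Dye orientation and slide therefore coincide. The labels do not name the pools, so the area number of an array on its slide (1 to 4) was taken as its pool pair, and 1 array whose title reads area 1.2 was taken as area 1.

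The deposited scanner files give intensity per spot, per the file headers, as foreground and local background in the 532 nm (Cy3) and 635 nm (Cy5) channels, without background correction. The scanner software is not given in the sources used here. The deposited whole-series values are log2 ratios. The submitters' processing notes list limma without a version, and the background correction and normalisation behind the deposited values are not given in the sources used here. Set against the scanner intensities, the deposited log2 ratios ran as BHBH over BHBL on both slides, so no sign was turned. Their medians per array lay between -0.0142 and 0.0396, and their correlation across probes with the ratios computed here lay between 0.941 and 0.96. Those ratios were used only as an alternative.

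Each array held 45212 spots, of which 1418 were controls and 153 of these negative controls. The other 43794 were probes. Of these, 21790 carried 1 gene symbol (15229 distinct symbols) and 22004 carried none. Median foreground and background intensities were read in R 4.3.3 with jsonlite 2.0.0 and the data.table package (version 1.17.8) and processed with limma 3.58.1. Background was corrected with normexp (offset 50), and log2 ratios were normalised within arrays by loess with control spots at weight 0. Each ratio was turned to BHBH over BHBL by the labelled dyes, and both arrays of a pool pair were averaged, which cancels the joint effect of dye and slide. A probe was kept if its signal exceeded the mean plus 2 SD of the negative controls in either channel on at least 4 of 8 arrays, which left 37884 probes. A gene was represented by its kept probe with the highest mean log2 intensity. The 32448 features tested were 14084 named genes and 18364 probes without a symbol. Symbols are those of the array annotation, with older list symbols matched through aliases of the RefSeq gene table. No coordinates are given.

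The 4 averaged ratios were tested against 0 with limma (lmFit and eBayes), and p was adjusted by the Benjamini-Hochberg method over all features. A feature was called at adjusted p under 0.05. A looser count, of features at unadjusted p under 0.05 with at least a 1.5-fold difference, is given as a value and not as a set of calls. The same averages were used in camera with a preset correlation of 0.01 for 29 gene lists, adjusted over the lists, and again with a correlation estimated from the data and with fry. Of 894 distinct symbols on these lists, 785 were measured. Errors are standard errors from limma over 4 pool pairs unless another error is named. The number of arrays limits the precision of every value.

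The named genes follow a rule with 4 parts. The first part takes the 10 largest called differences per direction. The second fills each direction up to 10 with the smallest unadjusted p among genes with the same sign on all 8 arrays and at least a 1.5-fold difference. The third takes up to 4 members of each list by unadjusted p, and the fourth is a set of 28 genes of steroid synthesis, metabolism and other cell types. The lists, this rule, the tests and the alternatives were fixed before the data were examined, and exceptions are named where they appear. Among 147 named genes, 35 had further kept probes, and for 5 of these (CYP19A1, ETFA, CIDEB, BMPR2 and RPL14) no further probe had the sign of the probe used.

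Alternatives covered background correction, normalisation, the deposited log2 ratios, the probe filter, the mean of all probes of a gene, fits of the 8 arrays with and without the area number as a replicate block, each slide alone, separate channels, the variance model, array weights, and each pool pair left out in turn. Mean pixel intensities, named genes alone, the removal of saturated probes and camera with an estimated correlation and 1 pool pair left out were added after the data were seen. The procedure was tested on simulated data with the layout of the real comparison of BHBH with BHBL, 32448 features and 50 changed genes per fold size. The averaged ratios recovered 2% of genes changed 1.5-fold, 40% at 2-fold, 94% at 4-fold and 96% at 8-fold, and 1.69% of all calls were unchanged genes. With the area number as a random replicate block, 28.6% of the calls were unchanged genes, and with the 8 arrays as separate ratios 50.7% were. The averages had been set as the reported fit in advance, and the blocked values are given beside them. In the same data camera with the preset correlation called the 1 list moved 1.5-fold and 0 of 30 unmoved lists. Camera with an estimated correlation and fry were not tried on simulated data, so whether they would call a moved list is not known. The simulated genes were drawn independently of one another, so false calls from correlation among members of a list were not tested. In the real data that correlation was estimated at 0.612 for the interferon list. On the real scanner intensities, 200 of 200 probes raised 8-fold in BHBH came out higher. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

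Signal over background sets the depth of an array. Between 67.1% and 81.5% of the probes exceeded the threshold in a channel, and 5 to 63 probes per channel were saturated. Probes above no threshold, control spots and coordinates were left out.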

Results

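Gene expression was measured in granulosa cells of dominant follicles from dairy cows early after calving, with the question of how the severity of negative energy balance bears on the cells' transcriptome. Group BHBH (severe negative energy balance) and group BHBL (mild) each comprised 4 pools of 3 cows. One BHBH pool and one BHBL pool shared each array, on 2 arrays with exchanged dyes, so that 8 arrays gave 4 pool pairs. All ratios are log2 of BHBH over BHBL, and n = 4 pool pairs throughout.

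Ratios of pool pairs differed from one another. Ratios of arrays that share an area number correlated across genes at r = 0.526 to 0.746, those of arrays of different areas on different slides at -0.444 to 0.274, and those of different areas on the same slide, where dye and slide are shared, at -0.2449 to 0.508. After the mean of each slide was removed, ratios of arrays that share an area number correlated across genes at r = 0.842 to 0.892, against -0.52 to -0.0299 for different areas on different slides and -0.5616 to -0.0935 for different areas on the same slide, where removing the mean of 4 arrays by itself lowers the values between areas. By these values 8 of 8 arrays matched best with the same area on the other slide. Between averaged pool pairs the correlation across genes ranged from -0.386 (pairs 1 and 4) to 0.429 (pairs 2 and 3). Genes are not independent replicates in these values. At least 2-fold differences numbered 950 higher and 842 lower in pair 1, 360 and 1190 in pair 2, 524 and 779 in pair 3, and 390 and 1645 in pair 4.

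The rule named 10 genes as lower in BHBH. It demands the same sign on all 8 arrays, so each of them was lower in every pool pair by selection. WFDC2 (probe EMBV3_33948), a secreted protein with protease inhibitor domains, was 6.35-fold lower (log2 -2.67 ± 0.15 SE, n = 4), and AGR2 (EMBV3_28884), a disulfide isomerase of secretory cells, was 8.58-fold lower (-3.10 ± 0.31). ADA (EMBV3_04116), adenosine deaminase, was at -1.40 ± 0.09 and F11R (EMBV3_10548), a junctional adhesion molecule, at -1.87 ± 0.20. The cadherin CDH26 (EMBV3_11415) was at -2.39 ± 0.27 and the retinol dehydrogenase DHRS9 (EMBV3_31623) at -1.95 ± 0.22. A further probe of F11R was at -0.347 and a further probe of DHRS9 at -0.0994. LOC784768 (EMBV3_17777) had the lowest ratio of the 10 genes named here by the rule, -4.84 ± 0.51. LOC100296105, TMEM217 and FAM174B completed the 10, between -2.10 and -0.85. In BHBH the probes of AGR2, LOC100296105 and TMEM217 were above background on 6, 4 and 3 of 8 arrays. No gene among the 10 passed the adjustment over all features, with adjusted p from 0.405 to 0.714.

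In the other direction 8 genes met the rule. The neuronal guidance phosphoprotein DPYSL2 (EMBV3_16507) was at 0.67 ± 0.10 and the matrix proteoglycan VCAN, versican (EMBV3_30781), at 0.92 ± 0.21. The receptor GPR85 (EMBV3_00203) was at 1.39 ± 0.36 and the small GTPase RAB38 (EMBV3_31443) at 1.04 ± 0.29. ATP6V1G2, SCAI, GLT25D1 and C5H12orf45 lay between 0.60 and 0.66. Further probes averaged 0.297 for DPYSL2 (1 of 2 higher) and 0.219 for C5H12orf45. All 8 were higher on 8 of 8 arrays, as the rule demands, with adjusted p of 0.866 to 0.919.

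**Figure D1:**
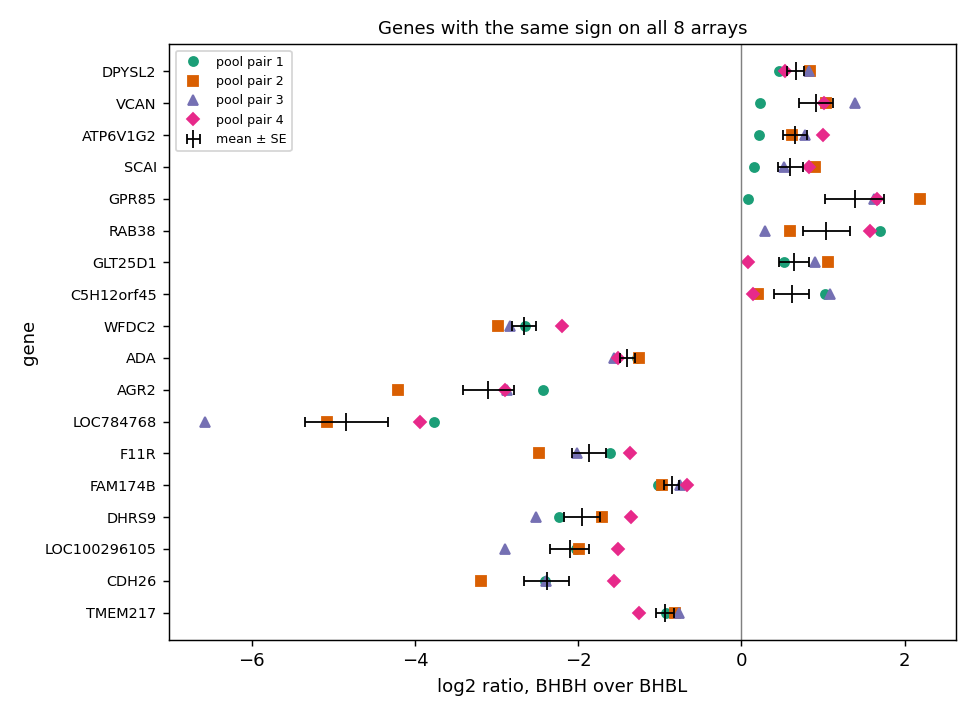
Log2 ratio of BHBH over BHBL (horizontal axis) for the 18 genes with the same sign on all 8 arrays that the rule named; symbols are the 4 pool pairs and bars the mean ± SE. The 10 lower genes reach -4.84 for LOC784768 and the 8 higher genes reach 1.39 for GPR85.

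Across all 32448 features, 56 were at least 2-fold lower in BHBH in every pool pair, 39 of them named genes, and 0 were at least 2-fold higher in every pair. Genes of this set chosen after their values were seen were the tight junction gene CLDN4 (-3.44 ± 0.43), the cell surface mucin MUC1 (-3.14 ± 0.43), the keratin KRT7 (-2.66 ± 0.39) and the antimicrobial peptide genes LAP (-2.99 ± 0.47) and TAP (-2.49 ± 0.38). All 56 were lower on all 8 arrays. Without pair 1 the counts were 224 lower and 4 higher, without pair 4 they were 108 lower and 59 higher, and with the deposited ratios 35 lower and 0 higher. Beside it, 3 lists of epithelial genes written after this set was seen had medians of -0.213, -0.208 and -0.269.

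With limma on the 4 averaged ratios, 0 features were called at adjusted p under 0.05, and the smallest adjusted p was 0.405. At unadjusted p under 0.05 there were 1654 features, or 5.1%. With the area number as a random replicate block, 97 features were called, 3 higher and 94 lower, which include all 10 lower genes above and 1 of the 8 higher ones (DPYSL2). Of the 97, 50 belong to the set of 56. The 8 arrays as separate ratios gave 165 calls, and every other fit gave 0, with smallest adjusted p between 0.0829 and 0.979. Features at unadjusted p under 0.05 and at least 1.5-fold numbered 495, 29 higher and 466 lower (94.1% lower), and 824 with the replicate block. With the sign of pair 1 turned there were 1113, of which 767 went one way. Without pair 1 that count was 1214, of which 980 were lower, and without pair 4 it was 922, of which 477 were lower. The same sign in all 4 pairs was seen for 4873 features (15%), where chance gives 12.5%.

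Genes of the immediate early response, which are transcribed within minutes of a stimulus, were lower in BHBH as a list. The median of 28 measured members was -0.51, with 25 lower on average, and camera gave adjusted p = 4.51e-08, but adjusted p = 0.831 with an estimated correlation and 0.859 with fry. Among its members ATF3 (-1.85 ± 0.29), FOSB (-0.79 ± 0.14) and the phosphatase gene DUSP5 (-0.81 ± 0.12) passed when adjusted over the list alone, at adjusted p of 0.0221, 0.0289 and 0.0221. Further probes of FOSB averaged -0.256. None of the other 25 passed, and HBEGF was at -0.53 ± 0.13, above background in BHBH on 3 of 8 arrays. Genes of the interferon response were lower as a list too. Of 31 measured members 30 were lower on average, the median was -0.453 and adjusted p = 8.96e-08, but adjusted p = 0.831 with an estimated correlation and 0.859 with fry. ISG15 (chosen, like KLF4, after its value was seen) was at -1.29 ± 0.44, GBP4 (above background in BHBH on 6 of 8 arrays) at -1.37 ± 0.35, IFI44 at -0.70 ± 0.16 and MX1 at -0.62 ± 0.15, and 0 members passed when adjusted over the list alone. KLF4 was at -1.44 ± 0.36.

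Both list medians were carried by pairs 2, 3 and 4. The immediate early medians were 0.188, -0.848, -0.319 and -1.27 in pairs 1 to 4, and the interferon medians 0.145, -0.999, -0.191 and -1.1. Leukocyte markers had medians of 0.939, -0.0633, 0.616 and -2.12 in the same pairs. Of the epithelial lists written after the set of 56 was seen, general epithelium had medians of 0.0523, -0.511, -0.296 and -0.229. Squamous epithelium had 0.0044, -0.661, -0.133 and -0.0546, and glandular epithelium -0.102, -0.651, -0.144 and -0.138. ATF3 is 1 of the 56. Neither call held in camera with an estimated correlation, where no list lay below adjusted p = 0.831. How far correlation among members accounts for that loss was not tested.

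Cell cycle and DNA replication genes were higher in BHBH as a list. Of 48 measured members 42 were higher on average, with a median of 0.197 and adjusted p = 1.36e-05 in camera, but adjusted p = 0.831 with an estimated correlation. The mitotic kinesin KIF11 was at 0.55 ± 0.11, the phosphatase gene CDKN3 at 0.64 ± 0.18 and the kinase gene AURKB at 0.71 ± 0.29, with further probes at averages of 0.248 for CDKN3 and 0.0985 for AURKB. The ovulation and luteinisation list, genes that follow the gonadotrophin surge, was lower, with 20 of 26 members lower on average, a median of -0.331 and adjusted p = 0.0215, but adjusted p = 0.831 with an estimated correlation. PLAT, tissue plasminogen activator, was at -1.50 ± 0.21 and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0243). The prostaglandin-degrading enzyme gene HPGD was at -1.61 ± 0.34 (4 further probes averaged -0.383), and TNFAIP6, a cumulus matrix gene, at 0.48 ± 0.18. Pair medians were -0.365, 0.657, 0.199 and 0.618 for the cell cycle, beside -0.514, 0.336, 0.0665 and 0.536 for the granulosa list. For ovulation they were 0.166, -0.684, -0.155 and -0.415, beside 0.18, -0.302, -0.108 and -0.327 for theca and stroma markers. The general epithelium list had the signs of the ovulation list in every pair, as did further lists, among them extracellular matrix and TGF-beta signalling. Without pair 2 adjusted p was 0.202 for the cell cycle and 0.0584 for ovulation, without pair 4 it was 0.52 for ovulation, and over all 24 fits it ranged from 3.4e-16 to 0.202 and from 6.24e-06 to 0.52. Over the 29 lists camera called 4, 1 higher and 3 lower, against 9 with the replicate block, 12 without pair 1 and 0 with an estimated correlation.

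**Figure D2:**
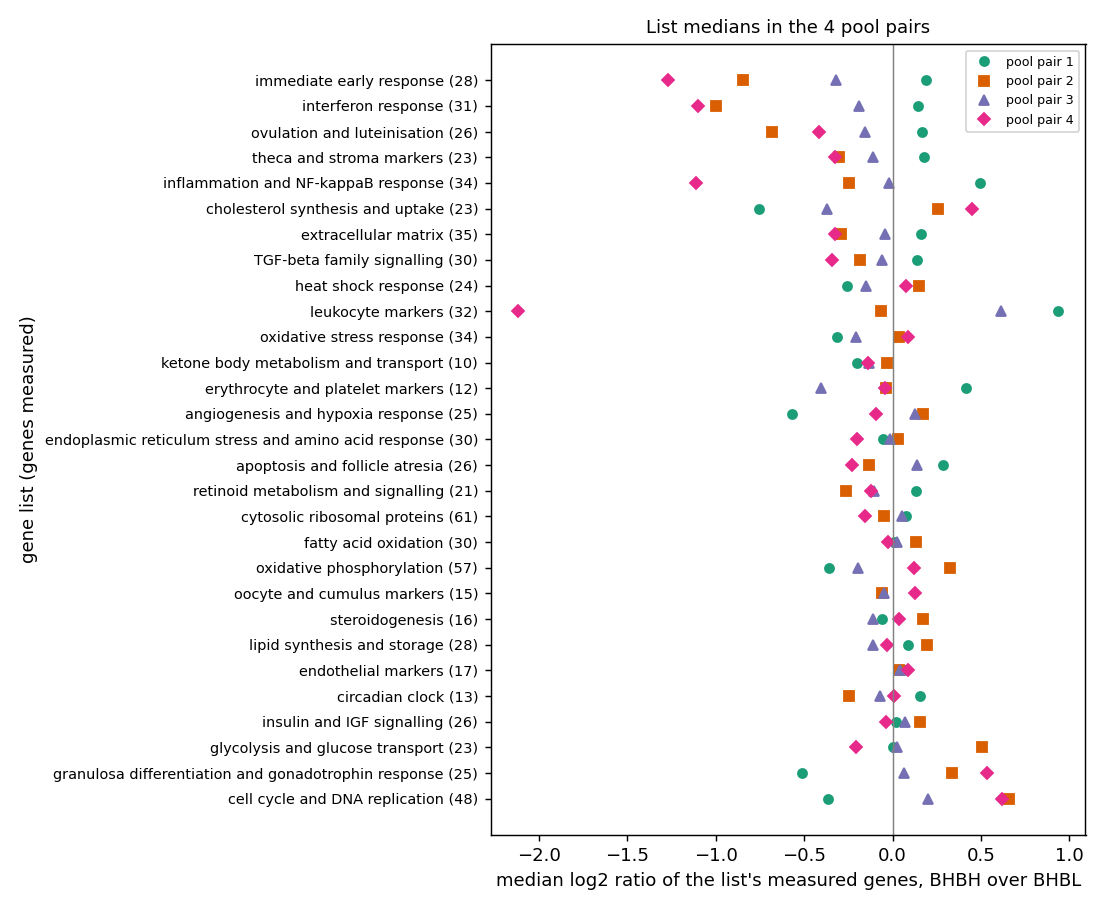
Median log2 ratio of BHBH over BHBL (horizontal axis) of each of the 29 gene lists, with the number of measured genes in brackets; symbols are the 4 pool pairs and lists are ordered by their median. Leukocyte markers span from -2.12 in pair 4 to 0.939 in pair 1, and the immediate early list from -1.27 to 0.188.

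Steroid synthesis genes had no common direction. The 16 measured members had a median of 0.0152 (adjusted p = 0.795), and 0 passed when adjusted over the list alone. CYP19A1, aromatase, was at -0.21 ± 0.55, with pair ratios of -1.35, 0.63, -1.41 and 1.27, and its other 2 probes averaged 0.39, of opposite sign. STAR, the cholesterol transporter of steroidogenic mitochondria, was at 0.36 ± 0.76, from 3.10 in pair 1 to -1.36 in pair 4. CYP11A1 was at -0.37 ± 0.63 and HSD3B1 at -0.16 ± 0.39. These differences were smaller than the spread between pool pairs.

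Granulosa cell genes had opposite signs in different pool pairs. The list of differentiation and gonadotrophin response genes had 25 measured members, 8 of them lower on average, and a median of 0.118 (adjusted p = 0.128), with pair medians of -0.514, 0.336, 0.0665 and 0.536. Without pair 1 adjusted p was 4.03e-05 with the preset correlation, but adjusted p = 0.546 with an estimated correlation, and over all 24 fits it ranged up to 1. FSHR, the follicle stimulating hormone receptor, was at 0.32 ± 0.64, with -1.55 in pair 1 and 1.99 in pair 4. LHCGR was at 0.46 ± 0.35 (further probe 0.14) and the granulosa transcription factor gene FOXL2 at 0.24 ± 0.14. The inhibin genes INHA (0.12 ± 0.09) and INHBA (0.07 ± 0.20) were saturated on several arrays, which limits their ratios.

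Genes that handle the fuels of energy shortage did not pass the test as lists. Ketone body genes (10 measured) had a median of -0.0627 (adjusted p = 0.538), with BDH1, beta-hydroxybutyrate dehydrogenase, at -0.10 ± 0.09 and OXCT1 at -0.09 ± 0.08. The BDH1 probe was above background on 2 of 8 arrays in BHBH and 4 of 8 in BHBL, so its ratio says little about the gene. Fatty acid oxidation genes (30 measured) had a median of -0.0144 (adjusted p = 0.795), with CPT1A at -0.09 ± 0.21. PDK4, which spares glucose, was at -0.22 ± 1.18, with 0.80, 1.44 and 1.57 in pairs 1 to 3 and -4.69 in pair 4. The macrophage genes CD163 (0.85, 2.31, 1.67 and -4.72) and CD14 (2.95, 1.47, 1.25 and -3.46), chosen after their values were seen, had the same signs in these pairs. Oxidative phosphorylation genes (57 measured, median -0.0137) had pair medians from -0.36 to 0.323, and COX7B was at 0.37 ± 0.07. In 0 of these 3 lists did a member pass when adjusted over the list alone.

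Nor did the lists of lipid and sugar metabolism. Cholesterol synthesis and uptake genes (23 measured) had a median of -0.149 (adjusted p = 0.137), with 18 lower on average and PMVK, an enzyme of the mevalonate pathway, at -0.32 ± 0.09 (further probe -0.0544). Lipid synthesis and storage genes had a median of 0.016, with the lipolysis cofactor gene ABHD5 at -0.84 ± 0.25 and the droplet coat gene PLIN2 at 0.21 ± 0.30. ANGPTL4 was at -0.02 ± 0.11. Glycolysis and glucose transport genes had a median of 0.0914 (adjusted p = 0.313), and the glucose transporter gene SLC2A1 was at -0.34 ± 0.12 (further probe -0.0388). Insulin and IGF signalling genes (26 measured) had a median of 0.0359. FOXO1, a target of insulin signalling, was at 0.46 ± 0.16 and higher in 4 of 4 pairs, and PAPPA, a protease of IGF binding proteins, was at 0.23 ± 0.07. IGF1 was at 0.02 ± 0.10, IGFBP2 at 0.05 ± 0.10 and IGFBP5 at -0.41 ± 0.92, above background on 7 of 8 arrays in BHBH and 6 of 8 in BHBL. No member of these 4 lists passed when adjusted over the list alone.

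Markers of other cell types varied between pools. Leukocyte markers (32 measured) had a median of -0.115 (adjusted p = 0.223), with PTPRC, the pan-leukocyte phosphatase CD45, at -0.34 ± 0.45 and the neutrophil gene S100A8 at -2.54 ± 0.75. Without pair 4 the leukocyte list was higher in BHBH (adjusted p = 1.79e-05 with the preset correlation, but adjusted p = 0.937 with an estimated correlation). Without pair 1 it was lower (adjusted p = 0.0011, but adjusted p = 0.675 with an estimated correlation). Red cell and platelet markers had a median of -0.062, and HBB, beta-globin, had ratios of 4.10, -4.98, -3.89 and 0.43. Theca and stroma markers had a median of -0.234 (adjusted p = 0.137), with CYP17A1, the androgen-synthesis enzyme of theca cells, at -0.21 ± 0.08 and the stromal proteoglycan gene LUM at -1.32 ± 0.42. Endothelial markers had a median of 0.0308, with PECAM1 below the probe filter, and oocyte and cumulus markers 0.00725. VNN2, a pantetheinase gene, was at -1.99 ± 0.92, with -3.14 and -4.71 in pairs 2 and 3.

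**Figure D3:**
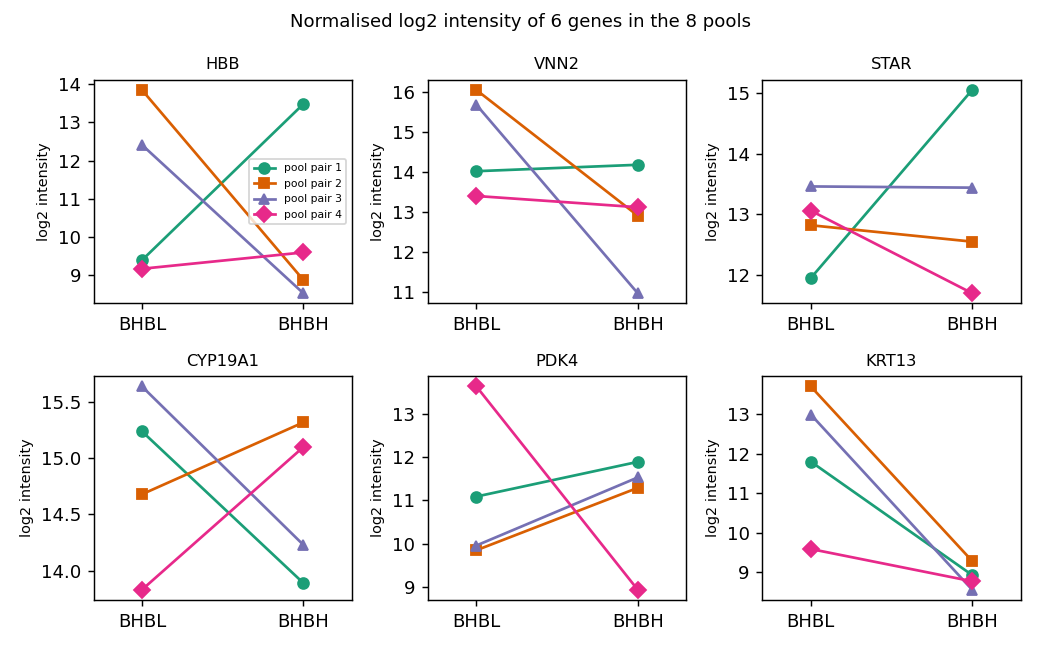
Normalised log2 intensity (vertical axis) of 6 genes in the BHBL and BHBH pool of each pool pair; lines join pools that shared arrays. STAR is higher in BHBH in pair 1 (log2 ratio 3.10), PDK4 is lower in pair 4 (-4.69), and HBB is highest in BHBH pool 1 and BHBL pools 2 and 3.

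The joint effect of dye and slide, fitted on the 8 arrays beside the group term, was past adjusted p of 0.05 for 9315 features (28.7%). The group ratios of slide 289 and slide 288 correlated across features at r = 0.294. The 4 lists called by camera had medians on slides 289 and 288 of -0.443 and -0.573 for the immediate early list, -0.493 and -0.511 for interferon, -0.374 and -0.373 for ovulation, and 0.225 and 0.283 for the cell cycle.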

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

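Apart from the epithelial lists, the counts of calls and the looser counts under other splits, the tests of explanations in this part were chosen after the results they concern were seen. The 5 epithelial lists were written after the lower genes were seen, from genes not yet looked at. The criteria of the tests on red cells, exchanged pools and leukocytes were set once their own values had been seen, and the test on red cells took the place of a correlation of HBB with HBA, which was set aside because the pools fall in separate clusters.

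In 9 of 176 groups of 4 pool pairs (147 genes and 29 list medians) 1 pair lay far from the other 3, where chance alone gives about 1 in 20. Pair 1 stood apart in 3, pair 3 in 2 and pair 4 in 4. HPGD was at -0.328 in pair 1 against -2.11 to -1.99, CASP6 at -0.221 in pair 1 against -0.336 to -0.324, and the matrix gene SPARC at 0.637 in pair 1 against -1.28 to -0.983. SDHC was at -0.949 in pair 3 against -0.155 to -0.0598, and RPS10 at -1.56 in pair 3 against -0.267 to -0.127. MX1 was at -1.13 in pair 4 against -0.496 to -0.39, RPL21 at 0.843 in pair 4 against 0.126 to 0.247, and PDK4 at -4.69 in pair 4 against 0.796 to 1.57. The oocyte and cumulus list had a median of 0.128 in pair 4 against -0.0607 to -0.0496.

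The first pattern is the set of 56 features at least 2-fold lower in BHBH in every pool pair, in whose averages the joint effect of dye and slide cancels. All 56 were lower on all 8 arrays, and on each slide 48 were at least 2-fold lower on all 4 arrays. Dyes were exchanged between the slides, so an effect of dye or slide that adds to the log2 ratio cancels in the averages by which the 56 were chosen. The 56 were chosen on these same arrays, so their agreement between the slides is in part built in and is no separate support. Of features at least 2-fold lower on all 4 arrays of slide 289, 54 of 54 were lower on all 4 of slide 288. Of 73 so chosen on slide 288, 71.2% were lower on all 4 arrays of slide 289. A bias of dye or slide stays open for features outside the 56. A smaller share of granulosa cells in the BHBL pools would raise granulosa genes in BHBH. The granulosa list's median lay above 0 in 3 of 4 pairs and at -0.514 in pair 1, which goes against it there. That list holds genes of differentiation and gonadotrophin response, so it does not measure cell share alone. Epithelial cells carried over at aspiration, more of them in the BHBL pools, are a candidate explanation: 3 of 3 lists, of general, squamous and glandular epithelium, had medians lower than all of 10000 random lists of like size and brightness, which do not carry the correlation among such genes. Among abundant members, ratios in pairs 1 to 4 were -1.71, -2.41, -4.14 and 0.31 for KRT78, 0.225, -1.75, -1.27 and -2.49 for DMBT1, -2.98, -4.22, -4.77 and -0.337 for MAL, and 1.59, 0.873, 0.00898 and -3 for CSTB. The comparison with random lists used averages over the 4 pairs. In pair 1 the 3 medians were 0.0523, 0.0044 and -0.102, which goes against this explanation there for the general and squamous lists. Keratin genes chosen after their values were seen went both ways in pair 1. KRT8, KRT18 and KRT19 were higher in BHBH there (3.975, 3.745 and 0.20) and lower in pairs 2, 3 and 4. KRT7, KRT4 and KRT13 were lower in pair 1 (-2.44, -2.41 and -2.87). The ciliated list (-0.023) and the mesothelial list (-0.078) lay at percentiles 37.6 and 13.1. Of 38, 35 and 28 genes 57.9%, 62.9% and 53.6% were above background in BHBH on all 8 arrays against 64.8% of all features. A lower expression of these genes by the granulosa cells themselves with severe energy shortage stays open and was not tested.

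The second pattern is pair 1, whose ratios correlated across genes at -0.386 with pair 4 and -0.145 with pair 2. An exchange of its 2 pools stays open. Of 224 features at least 2-fold lower in pairs 2, 3 and 4, 51.3% were higher in pair 1. There 57 were at least 2-fold higher and 56 at least 2-fold lower. The exact 95% interval of 44.6 to 58.1 takes features as independent. Features of 1 pool pair are not, so the interval measures no spread between pools and can not decide. With pair 1 turned, 5 features would be called in place of 0, 1113 would be loose in place of 495, and 15 lists would be called in place of 4. For the globin genes alone, red cells carried over with blood may account for the signs, since the 3 pools with the most HBB (log2 12.41 or more, others 9.59 or less) were also the 3 with the most HBA, namely BHBH pool 1 and BHBL pools 2 and 3. Both are globin genes, so their agreement does not test the source. ALAS2, another gene of the red cell list, went with them in part. It was at 8.29 and 8.06 in BHBL pools 2 and 3, but at 7.73 in BHBH pool 4 and 7.46 in BHBH pool 1. A difference between the cows of these pools was not tested.

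The third pattern is the lower immediate early and interferon genes. Leukocytes carried over stay open in all 4 pairs. The criterion excluded them only where every marker was higher in BHBH, which could hardly be met, so it decides little. In pair 3 the leukocyte median was 0.616, with 24 of 32 markers higher in BHBH. There 19 of 31 interferon and 18 of 28 immediate early genes were lower, which goes against leukocytes as a whole without excluding them. S100A8 and S100A9, which squamous epithelium expresses too, were at -4.70 and -4.55 in pair 3. Kinds of leukocytes were not tested apart. In pairs 1, 2 and 4 both list medians had the sign of the leukocyte median in 3 of 3 pairs, but in pair 2 the leukocyte median was -0.0633, with 17 of 32 markers lower against 31 of 31 interferon and 25 of 28 immediate early genes, which goes against leukocytes there without excluding them. The general and squamous epithelial lists had the same signs as both lists in every pair, though the squamous median was 0.0044 in pair 1. The glandular list had a median of -0.102 in pair 1, of opposite sign, and the same signs in pairs 2, 3 and 4. Other lists had the signs of both lists in every pair too. They were the ovulation, retinoid, extracellular matrix, TGF-beta, inflammation, theca and stroma, and red cell and platelet lists. Shared signs therefore do not single out epithelial cells. Epithelial cells were not tested here, and the difference in energy balance stays open too.

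Other splits of the samples bear on the counts. Under the 8 sign patterns of the 4 ratios, too few for a share under 0.05, the loose count of 495 was reached by 4 patterns (highest other 1192), the 0 calls by all 8 (highest other 5), the 4 called lists by 7 (highest other 15) and the 56 features at least 2-fold one way in every pair by 3 (highest other 59, with pair 4 turned, and 57 with pairs 2, 3 and 4 turned). On separate channels, 15 of the 35 splits of the 8 pools gave as many loose features as the real split (433, highest other 2824), 35 gave as many calls (0, highest other 2309) and 22 as many called lists (4, highest other 17). Every split reaches 0 calls, so that comparison says nothing, and chance can not be excluded for the loose count and the called lists. The split of area numbers 1 and 2 against 3 and 4 called the 2309 features, and whether this lies in the samples or in the arrays and areas they share was not tested. Of the 8 splits that part all 4 array pairs, as the real one does, 4 gave as many loose features, with 943 the highest other, while splits that part fewer pairs reached 2824.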

How the results depend on the processing

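Mean pixel intensities, named genes alone, the removal of saturated probes and the estimated correlation with 1 replicate left out were chosen after seeing the data. The 0 calls held in 21 of 23 alternatives. The exceptions were 97 with the replicate block and 165 with the 8 arrays as separate ratios; on simulated data these fits called unchanged genes (28.6% and 50.7% of their calls). The looser count (495) stayed within 362 to 721 in 14 of 23. It was 797 with separate ratios, 824 with the replicate block, 994 on slide 289 alone, 1776 on slide 288 alone, 261 with trend and robust variance, 296 with mean pixel intensities and 319 among named genes alone, where fewer features were tested. Leaving out 1 replicate gave 379 to 1214, the latter without pair 1. Without pair 4 it was 922, with 51.7% lower in place of 94.1%. Called lists (4) became 7 with the strict filter, 7 with array weights, 9 with the replicate block, 0 with an estimated correlation, whether on all pairs or with 1 replicate left out (0 to 0), 0 with fry's directional test and 5 to 12 with 1 replicate left out. Members of the lists passing were 0 over all features and 7 adjusted over the list alone. The cause was not tested in the other cases. With the preset correlation the immediate early and interferon lists were called in 24 of 24 fits, cell cycle in 23 and ovulation in 18, and all 4 calls were lost with an estimated correlation and with fry. Of the other 25 lists, 11 were called in 1 to 6 of these fits, inflammation most often. List medians stayed within the spread between pairs in 660 of 667 values and named genes in 3270 of 3344, and no called list reversed. Fits that change only the variance model or the replicate block leave the ratios as they are. Leaving out 1 pair can not move the mean ratio of a gene beyond that spread. These shares therefore say little about robustness. Signal limits dim genes: BDH1 was above background in BHBH on 2 arrays and TGFB2 on 0. With its BHBH signal raised to at least the lowest level above background, TGFB2 was 1.92-fold lower on average. Its ratios in pairs 1 to 4 were -0.597, -1.57, -1.46 and -0.549, so that fold did not hold in every pair.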

Other observations

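The lists in this part were fixed in advance, and the genes named by pool in the next paragraph were chosen after their values were seen. Stress and inflammation genes included single members with lower ratios in every pair. HSPA1A, an inducible heat shock chaperone, was at -1.01 ± 0.14 and passed when adjusted over the list alone (adjusted p = 0.0195), while the heat shock list had a median of -0.128 (adjusted p = 0.137). CXCL5, a neutrophil chemokine, was at -2.70 ± 0.34 (0.0209 adjusted over the list alone), and the inflammation list had a median of -0.176 (adjusted p = 0.113, called in 6 of 24 fits, but adjusted p = 0.867 with an estimated correlation), with LTF at -2.21 ± 0.60. DHRS9 was the 1 member that passed in the retinoid list (0.00716 adjusted over the list alone, with a further probe at -0.0994). There RDH10 (above background in BHBH on 5 of 8 arrays) was at -0.51 ± 0.18 and the list median was -0.0412. For this list fry gave adjusted p = 0.00117 for changes in either direction, but 0.859 in its directional test. How far the former rests on DHRS9 alone was not tested. ATF3 passed in the endoplasmic reticulum stress list too (0.0473 adjusted over the list alone), whose median was -0.0509, with DNAJB9 at -0.59 ± 0.15. Medians were -0.091 for oxidative stress, -0.0486 for apoptosis and atresia, -0.131 for the extracellular matrix, -0.128 for TGF-beta signalling, -0.0555 for angiogenesis and hypoxia, 0.0323 for the circadian clock and -0.0398 for cytosolic ribosomal proteins, with adjusted p from 0.223 to 0.912, and 0 members of these 7 lists passed when adjusted over the list alone.

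Single pools stood apart in some genes. TIMP1, a metalloproteinase inhibitor, had a log2 level of 14.68 in BHBH pool 1 and 8.62 to 9.73 in the other BHBH pools, and STAR was at 15.05 there against 11.7 to 13.44. IGFBP5 was at 9.83 in BHBH pool 1 and 9.82 in BHBL pool 4, and between 6.99 and 8.14 in the other 6 pools. The keratin gene KRT18 was at 11.86 and 12.18 in those 2 pools and at 10.44 or less elsewhere. FST, an activin antagonist gene, was at -1.70 in pair 1 and at 2.13 in pair 4, and AMH, the anti-Mullerian hormone gene, at -1.18 and 1.76. CD163, a macrophage scavenger receptor gene, was at -4.72 in pair 4 and at 0.85, 2.31 and 1.67 in pairs 1, 2 and 3. VNN1 was at -4.88 and -4.96 in pairs 2 and 4 and at 2.17 in pair 3.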
